A study of Mus musculus and Danio rerio with 9 samples.

How the data were processed

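Small RNA sequencing of mouse NPCs was analysed, with 3 wild-type and 3 Nrep(miR-29scr) libraries. Per the labels, total RNA was taken up in Trizol and the libraries were built with the NEBNext Multiplex small RNA kit. The table used here holds whole-number counts per miRNA arm and genomic copy, as deposited, with 1471 miRNA rows and 1 row of totals. The totals equalled the column sums of the other rows exactly, so this row was removed before any test. Per the submitters' processing notes, CASAVA, TopHat2 2.0.6, DESeq2 and bedtools were used for the series, and the only genome build named is the zebrafish build danRer7. The mouse build, the aligner of the small RNA reads, the treatment of adapters and the rule for reads that match several copies are not given in the sources used here. The 3 zebrafish samples were not analysed here.

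Columns were assigned to the 6 libraries by genotype and replicate number. The design text names 1 line for each genotype. Whether the mutant libraries came from 1 clone or several, or from separate cultures or differentiations, is not given in the sources used here, so p-values measure the spread between these libraries, which may be technical. A difference between the genotypes also holds any other difference between the 2 lines. No 2 libraries of a group agreed within sampling noise, since the chi-square per degree of freedom between them was 382 to 6287.

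Totals ran from 15839017 to 43065652 counts. 3 counts, taken as the floor, equalled 0.0522 to 0.221 CPM depending on the library. Intervals and floors cover counting error only, because PCR copies were not marked. The biological coefficient of variation was 0.54, so the spread between libraries and not depth set the precision of all but the scarce rows.

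Rows were filtered with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total count 15), which left 781 rows. Libraries were scaled by TMM, with factors of 1.335, 1.046 and 0.9124 for wild-type and 0.9576, 0.9578 and 0.8552 for mutant libraries, and tested with edgeR's robust quasi-likelihood test under R 4.3.3. Standard errors were taken as the size of the log2 fold change over the square root of the F statistic. CPM are TMM-scaled, except list sums, which were divided by library totals alone. P values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. DESeq2 1.42.0 with its own size factors and limma-voom in limma 3.58.1 were alternatives, and 45 miRNAs had no adjusted p in DESeq2. Lists were tested with camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with an estimated correlation and the rotation test fry as alternatives. Ratios within a library used a pseudocount of 0.5 and exact two-sided permutation tests, adjusted over the 6 ratios. Ratios of the 2 arms were also screened with limma over hairpins with a mean of at least 1 CPM in each arm.

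Before the data were examined, 18 miRNA lists were fixed. They are the miR-29 family, neural lineage, pluripotent cell, let-7 and miR-98, miR-17 to 92 and its paralog clusters, imprinted Dlk1-Dio3 cluster, Sfmbt2 cluster, other reported targets of target-directed degradation, p53-linked miR-34 and miR-449, hypoxia-linked, muscle, blood, endothelial, epithelial, mesenchymal and liver cell markers, Hox cluster and sensory cluster. The 15 lists with at least 3 tested rows entered the set test. The named miRNAs were also fixed by rule: every miR-29 row, among miRNAs past an adjusted p of 0.05 with a mean of at least 10 CPM and no overlap between groups the 10 highest and 10 lowest, the 2 smallest p values of each list (all rows of a list too small for the set test), and the 5 most abundant miRNAs. The rule named 45 miRNAs, of which 0 came from its second part. miR-708, miR-204, miR-135a-2, miR-10a, miR-615 and the miR-27b cluster were named after their values were seen.

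Many miRNAs have several genomic copies with the same mature sequence, and their reads sit mostly in 1 copy row, so single copy rows such as miR-9-2-5p are uncertain and their sum was an alternative. miR-29a-3p and miR-29c-3p are also nearly identical in sequence. No genome was used. A RefSeq gene table of the assembly GRCm38.p6 served only for which miRNA genes neighbour each other, within 10 kb, and 723 of the 781 tested rows matched it.

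The alternatives were other scalings (DESeq2 size factors, totals, upper quartiles), other filters on low counts, DESeq2, limma-voom, the replicate number as a block, each library left out in turn, copies summed, miR-29a-3p as the scale for miR-29b and another pseudocount. After the data were seen, 3 were added: wild-type library 2 and mutant library 1 left out together, the pluripotent list level as a covariate, and the shares with each library left out. The tests were tried on simulated counts for 781 miRNAs, each drawn independently, with 200 of them changed by known folds. At the fitted spread 1.9% of edgeR calls and 9.66% of DESeq2 calls were miRNAs that had not been changed, and both made 0 calls when no miRNA was changed.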

Results

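Small RNA was profiled in mouse neural progenitor cells (NPCs) differentiated from the embryonic stem cell line ES14. 3 libraries came from wild-type cells and 3 from Nrep(miR-29scr) cells, in which the miR-29 site of the Nrep transcript was scrambled. They are called mutant libraries here. The wild-type libraries 1, 2 and 3 held 43065652, 37217101 and 24188003 miRNA counts, and the mutant libraries 1, 2 and 3 held 39263812, 22140770 and 15839017. The series also has 3 zebrafish samples taken at 72 hours after fertilization, a wild type, a deletion of the libra locus and an inversion of its conserved part, and these were not analysed here. Messenger RNA is not measured by small RNA libraries, so the level of Nrep itself was not analysed here.

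The comparison of mutant with wild-type NPCs asks whether the amount of miR-29, or of other miRNAs, differed when the miR-29 site of Nrep was lost. miR-29 is a family of miRNAs whose members share a seed sequence and whose guide strand is the 3p arm. miR-29a-3p stood at 338 ± 91.3 TMM-scaled CPM (SD, n = 3) in mutant NPCs and at 156 ± 33.0 in wild-type NPCs, which is 2.16-fold higher (log2 fold change 1.11, SE 0.30). miR-29b-1-3p, the row with 93.9% to 99.4% of the miR-29b-3p counts of each library, stood at 28.1 ± 11.4 CPM in mutant and at 11.2 ± 0.989 CPM in wild-type NPCs, 2.51-fold higher (log2 fold change 1.33, SE 0.36). For both miRNAs the 3 mutant libraries lay above the 3 wild-type libraries. Of the 7 tested miR-29 rows these 2 rose and 0 fell, adjusted over the list alone. Over all 781 tested miRNAs neither passed, with an adjusted p of 0.118 for each in edgeR's quasi-likelihood test, and both passed in DESeq2 at adjusted p values of 0.0162 for miR-29a-3p and 0.012 for miR-29b-1-3p.

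The other miR-29 rows did not pass in either tool. miR-29c-3p was at 7.42 CPM in mutant and 5.42 CPM in wild-type NPCs (log2 fold change 0.45, SE 0.40, edgeR adjusted p 0.544). The passenger strands had log2 fold changes of 0.62 for miR-29a-5p, -0.02 for miR-29b-2-5p and -0.19 for miR-29c-5p, and miR-29b-2-3p had -0.67. Counts per library were 8 to 40 for miR-29a-5p, 3 to 43 for miR-29b-2-3p, 28 to 125 for miR-29b-2-5p and 139 to 630 for miR-29c-5p. miR-29b-1-5p had 14, 8 and 3 counts in wild-type and 8, 1 and 2 counts in mutant libraries and was not tested. The set test did not call the miR-29 family as a whole (camera adjusted p 0.401). No miR-29 row passed over the list alone when libraries were scaled by their totals or by upper quartiles, or when any 1 library other than mutant library 1 was left out. The log2 fold change of miR-29b-1-3p was between 0.94 and 1.52 with 1 library left out.

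**Figure D1:**
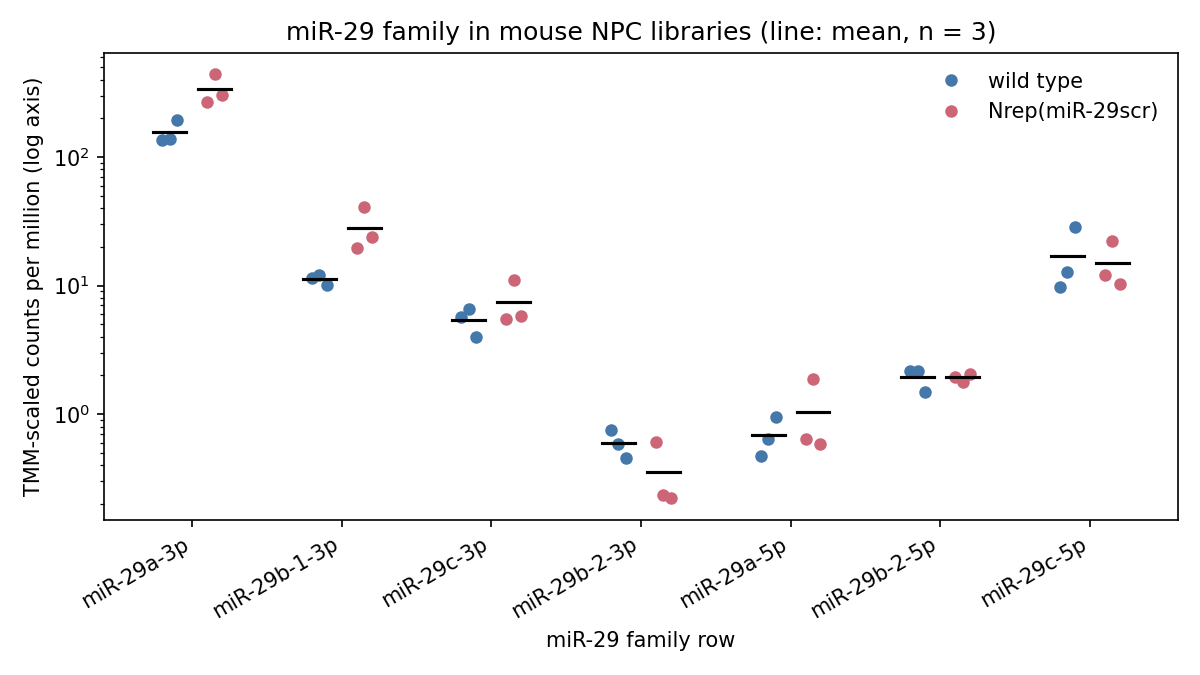
TMM-scaled CPM on a log axis for the 7 tested miR-29 rows, with 1 point per library, wild type in blue and Nrep(miR-29scr) in red, and a line at the mean of 3 libraries. The mutant points of miR-29a-3p and miR-29b-1-3p lie above the wild-type points, and those of the other rows overlap.

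Ratios of 2 miRNAs within a library do not depend on how libraries are scaled, and 6 such ratios were compared. The ratio of miR-29b-3p to miR-29a-3p differed by 0.11 ± 0.26 on the log2 scale (mutant minus wild type, SE, n = 3 in each group), which is less than its SE, with an exact two-sided permutation p of 0.8 (adjusted 0.9). The ratio of miR-29b-3p to miR-29b-5p, each pooled over both genomic copies, was 2.35-fold higher in mutant NPCs, a log2 difference of 1.23 ± 0.40, and all 3 mutant libraries lay above all 3 wild-type libraries (exact permutation p 0.1, Benjamini-Hochberg adjusted 0.3). Its 5p counts came mostly from the miR-29b-2 row and its 3p counts from the miR-29b-1 row. The row of a 3p read does not show which copy it came from. The ratio of miR-29b-3p to miR-29c-3p was higher by 0.80 ± 0.15, also in 3 of 3 mutant libraries (exact permutation p 0.1, adjusted 0.3). For miR-29a the guide to passenger difference was 0.65 ± 0.36 (exact permutation p 0.2, adjusted 0.3). The difference was 0.53 ± 0.66 for the guide to passenger ratio of miR-29c (exact permutation p 0.9, adjusted 0.9) and -0.69 ± 0.39 for miR-29c-3p to miR-29a-3p (exact permutation p 0.2, adjusted 0.3). The log2 ratio of miR-29c-3p to miR-29c-5p was -2.83 to -0.78 over the libraries. The arm taken as the miR-29c passenger thus outnumbered the guide in every library. With 3 libraries against 3 an exact permutation p cannot go below 0.1. Without wild-type library 3 the miR-29b-3p to miR-29a-3p difference turned to -0.14.

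The miRNAs of the imprinted Dlk1-Dio3 region, a large group of miRNAs expressed from the maternal chromosome and abundant in brain, were higher in mutant NPCs. All 57 tested rows had log2 fold changes above 0 with a median of 2.08, which is 4.22-fold. Of the 57, 51 rose and 0 fell adjusted over the list alone, while adjusted over all miRNAs 0 passed in edgeR and 47 passed in DESeq2. miR-411-5p rose from 13.4 ± 1.42 CPM to 74.3 ± 42.1 CPM (SD, n = 3), 5.56-fold, and miR-496a-3p rose 5.74-fold from 0.192 to 1.18 CPM, both past the test over the list alone. Summed over the list and divided by library totals alone, the region gave 490.2, 692.1 and 680.7 CPM in wild-type and 1992, 1084 and 3561 in mutant libraries. The camera set test called the list at an adjusted p of 1.33e-32 with a preset correlation of 0.01. With an estimated correlation its adjusted p was 0.673, and in the rotation test fry it was 0.144. Without wild-type library 2 and mutant library 1, which stood apart in other miRNAs, 52 of 52 tested rows were above 0 and 49 passed over the list alone. Over the list alone 0 passed without wild-type library 1 or without wild-type library 3, and 33 of 61 passed without mutant library 3, while every tested row stayed above 0 in these 3 fits, with medians of 1.87, 2.07 and 1.48.

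**Figure D2:**
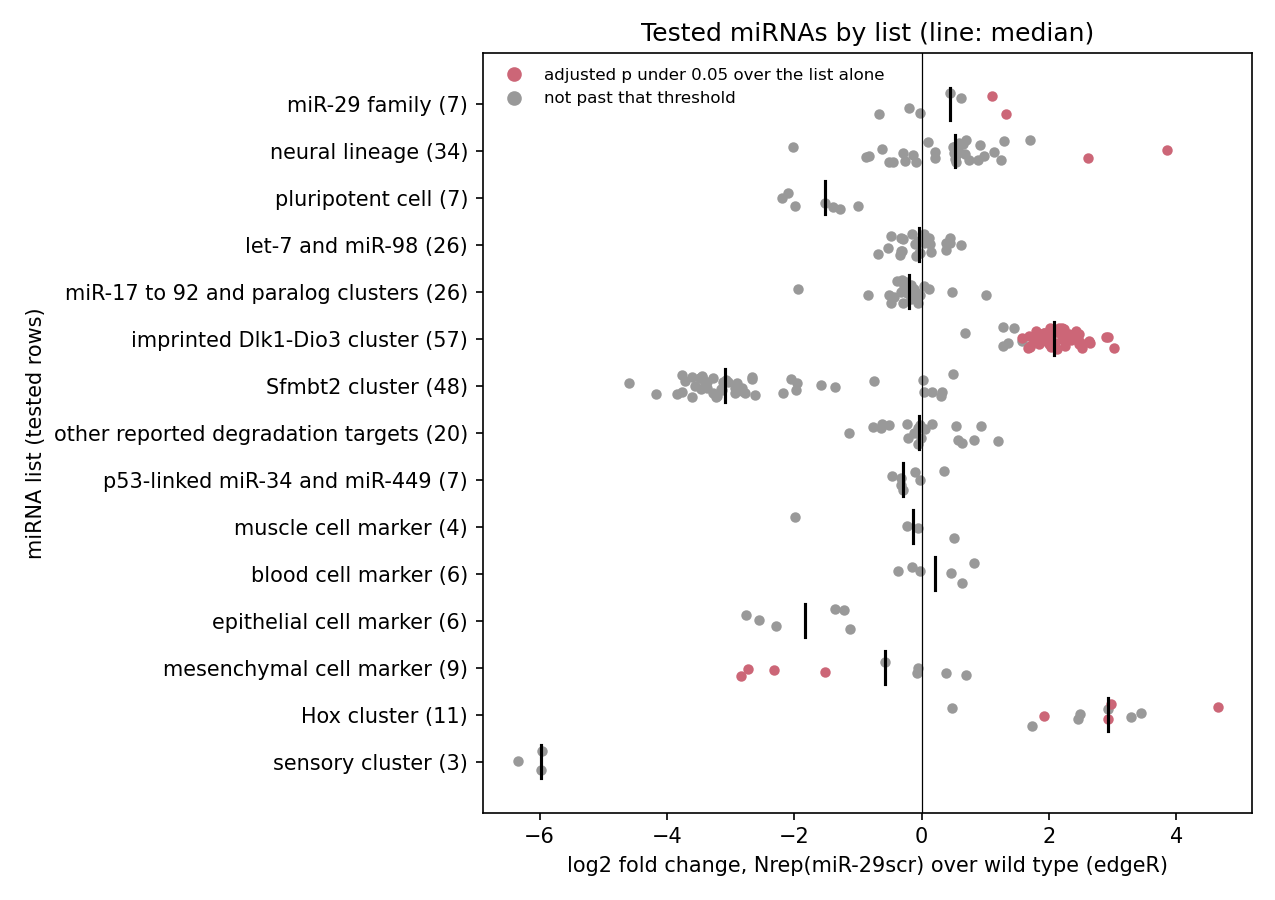
edgeR log2 fold change of mutant over wild-type NPCs for each tested miRNA in the 15 lists with at least 3 tested rows, with a line at the list median and red points for adjusted p under 0.05 over the list alone. All 57 Dlk1-Dio3 rows lie to the right of 0, and the Sfmbt2 rows have a median of -3.09.

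miRNAs hosted in the Hox gene clusters, which pattern the body axis, were also at higher levels in mutant NPCs. All 11 tested rows of miR-10, miR-196 and miR-615 were above 0 (median log2 fold change 2.93). 4 rose adjusted over the list alone (both arms of miR-10b, miR-10a-5p and miR-615-3p), while 0 fell and 7 did not pass. miR-10b-5p rose over the list alone from 4849 ± 2240 to 38297 ± 14135 CPM (SD, n = 3), 7.90-fold with a log2 fold change of 2.98 (SE 0.47) and an edgeR adjusted p of 0.0798 over all miRNAs. miR-10b-3p rose 7.64-fold. The list had a camera adjusted p of 0.000444, and its adjusted p was 0.813 with an estimated correlation. Without mutant library 3, the library with the highest sum for this list, the median was 1.47 and the camera adjusted p 0.035. Over the list alone 2 rose without that library, without wild-type library 2 or without wild-type library 3, and 8 rose without mutant library 2.

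Of 34 tested miRNAs of the neural lineage list, 24 were above 0 and 10 below, with a median log2 fold change of 0.53. 2 rose and 0 fell adjusted over the list alone, and these were the 2 arms of miR-219-2, a miRNA known for its part in oligodendrocyte differentiation. miR-219-2-3p rose 14.4-fold from 11.2 ± 10.2 to 161 ± 32.1 CPM (SD, n = 3), and the scarce row miR-219-2-5p rose 6.11-fold from 0.875 to 5.30 CPM. The row of the other genomic copy, miR-219-1-5p, did not pass (log2 fold change 0.49, edgeR adjusted p 0.317). The 6.11-fold rise thus holds for 1 copy row. miR-9-2-5p, a brain miRNA and the most abundant row in every library, was at 1.51-fold the wild-type level (edgeR adjusted p 0.204). Its other genomic copies give the same mature sequence and were counted in rows of their own, with miR-9-1-5p at 3.65 CPM in mutant and 4.03 CPM in wild-type NPCs (log2 fold change -0.13, edgeR adjusted p 0.907) and miR-9-3-5p at 40.6 and 18.4 CPM (log2 fold change 1.14, edgeR adjusted p 0.10, DESeq2 adjusted p 0.00443). With the copies summed the log2 fold change of miR-9-2-5p was 0.60 (edgeR adjusted p 0.190). The list had a camera adjusted p of 0.000757 and an adjusted p of 0.673 with an estimated correlation. Its call was lost without wild-type library 2 (camera adjusted p 0.115), and over the list alone 4 rows then rose and 3 fell. Over the list alone 0 passed without wild-type library 1 or mutant library 2, 1 rose without mutant library 3 and 4 rose without wild-type library 3.

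The miRNAs of the Sfmbt2 cluster, a large repeat-rich group inside an intron of the Polycomb gene Sfmbt2, were at lower levels in mutant NPCs on average, and this rested largely on wild-type library 2. The list takes every miR-297, miR-466, miR-467 and miR-669 row by name, and of its 48 tested rows 42 were below 0, with a median log2 fold change of -3.09. By neighbouring genes, 39 of these rows lay in the cluster from miR-467a-9 to miR-466l, and 38 of those were below 0. Adjusted over the list alone 0 passed, and over all miRNAs 0 passed in edgeR. DESeq2 gave an adjusted p for 17 of the 48 rows, and 5 of these passed. The sums, divided by library totals, were 1246, 25810 and 754.7 CPM in wild-type and 584.2, 588.8 and 449.1 in mutant libraries. miR-467a-9-5p was at 296, 13351 and 382 CPM in wild-type libraries 1, 2 and 3 and between 133 and 247 CPM in mutant libraries. The list had a camera adjusted p of 3.73e-05 and an adjusted p of 0.857 with an estimated correlation. Without wild-type library 2 its median log2 fold change was -0.42 and its camera adjusted p was 0.0174, and without wild-type library 3, 38 of 56 rows fell over the list alone. Many of these rows are near-identical copies, so counts of single rows are uncertain.

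Wild-type library 2 stood apart in further miRNAs. The pluripotent cell list holds the miR-290 to miR-295 cluster, which is abundant in embryonic stem cells, and also miR-302 and miR-367. It summed to 892.9 CPM of the library total in wild-type library 2 and 186.7 in mutant library 1. The sums were 1.556 and 2.108 in wild-type libraries 1 and 3 and 18.7 and 14.52 in mutant libraries 2 and 3. The 7 tested rows of this list were all of the miR-290 to miR-295 cluster, and 0 passed over the list alone. The set test was positive in sign (camera adjusted p 0.415), whereas the median fitted log2 fold change was -1.52. Without wild-type library 2 all 7 rows rose, adjusted over the list alone, and the camera adjusted p was 1.17e-05. The sensory cluster, miR-183, miR-96 and miR-182, summed to 13920 CPM of the library total in wild-type library 2 and to 8.15 and 373.5 in wild-type libraries 1 and 3, with 140.2, 14.45 and 20.39 in mutant libraries. 0 of its 3 tested rows passed over the list alone (camera adjusted p 0.415), and all 3 fell over the list alone without wild-type library 1 (camera adjusted p 0.0113). miR-182-5p was at 8854 CPM in wild-type library 2, at 255 CPM in wild-type library 3 and at 89.0 CPM in mutant library 1. Epithelial cell markers, such as miR-200c-3p at 8.29 CPM in wild-type library 2 and 1.23 to 1.90 CPM in the other 5 libraries, were below 0 in 6 of 6 tested rows, and 0 passed over the list alone (camera adjusted p 0.321).

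**Figure D3:**
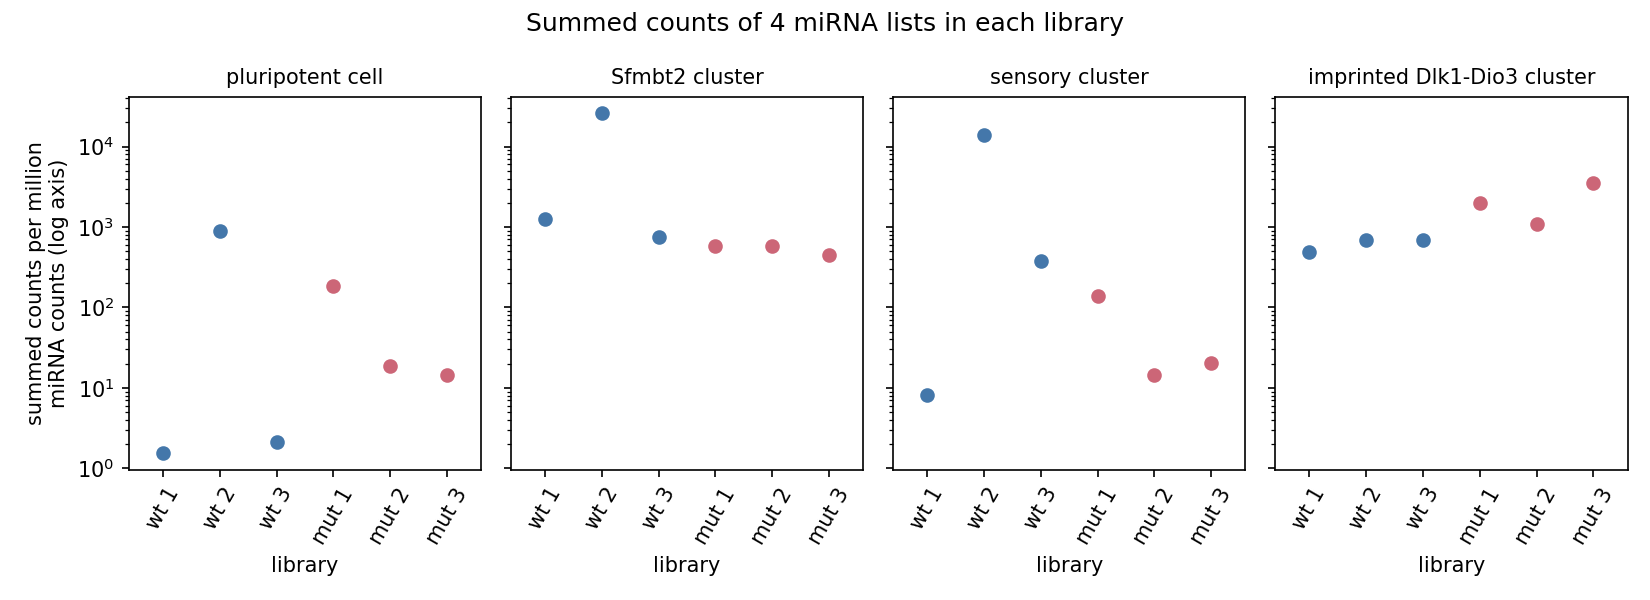
Summed CPM of the library total, on a log axis, of 4 miRNA lists in wild-type libraries (wt, blue) and mutant libraries (mut, red), with 1 point per library. Wild-type library 2 has the highest sum for the pluripotent cell list (892.9), the Sfmbt2 cluster (25810) and the sensory cluster (13920), and the 3 mutant libraries have the highest sums for the Dlk1-Dio3 cluster.

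Mesenchymal cell markers were mixed. Adjusted over the list alone, 4 of 9 tested rows fell, both arms of miR-199a-1 and of miR-214, and 0 rose (camera adjusted p 0.401). miR-199a-1-3p fell 2.86-fold over the list alone, from 1518 ± 615 to 531 ± 113 CPM (SD, n = 3). miR-214-3p fell 6.63-fold, with 9.88 CPM in wild-type library 1 and 83.5 and 83.6 CPM in the other wild-type libraries. With 1 library left out, 0 rows passed over the list alone, except without wild-type library 1, where 5 of 10 fell and the camera adjusted p was 0.00133.

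Other miRNAs reported as targets of target-directed degradation, the decay of a miRNA set off by extensive pairing to an RNA, were tested as a list of 20 rows (miR-7, miR-30b, miR-30c, miR-221, miR-222, miR-322, miR-335 and miR-503). Adjusted over the list alone 0 passed, 8 rows were above 0 and 12 below, and the camera adjusted p was 0.961. With totals as the scale, or without wild-type library 1, 1 row fell over the list alone. The smallest p values belonged to miR-335-3p, at 1651 ± 139 CPM in mutant and 3656 ± 1759 CPM in wild-type NPCs (edgeR adjusted p 0.150), and miR-7a-2-5p, at 3423 ± 283 and 5781 ± 1359 CPM (edgeR adjusted p 0.158). The let-7 and miR-98 list (26 tested, median log2 fold change -0.04, camera adjusted p 0.961) and the miR-17 to 92 list (26 tested, median -0.19, camera adjusted p 0.542) had 0 rows past the test over the list alone. Without wild-type library 3 the miR-17 to 92 list had a camera adjusted p of 0.0393, and 1 of its rows rose and 1 fell over the list alone. In the miR-17 to 92 list, miR-92b-3p was at 3294 ± 217 CPM in mutant and 1641 ± 391 CPM in wild-type NPCs (log2 fold change 1.01, edgeR adjusted p 0.10), and miR-19b-1-3p at 25.6 ± 3.39 and 98.6 ± 63.6 CPM (edgeR adjusted p 0.158). 0 rows passed over the list alone among p53-linked miR-34 and miR-449 (7 tested, camera adjusted p 0.791), muscle cell markers (4 tested, 0.763) and blood cell markers (6 tested, 0.542). In other settings 1 muscle row fell over the list alone, with totals, with upper quartiles or without wild-type library 1. Likewise 1 blood row rose without wild-type library 3. Hypoxia-linked miR-210 and endothelial miR-126, with 2 tested rows each, and liver miR-122, with 1, were too few for the set test. miR-210-3p was at 461 CPM in mutant and 669 CPM in wild-type NPCs, miR-126-3p at 96.8 and 112 CPM and miR-122-5p at 4.84 and 3.27 CPM, and none of these passed.

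Across all 781 tested miRNAs, 0 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, where the smallest adjusted p was 0.0753. At an unadjusted p under 0.05 there were 164, of which 95 were higher and 69 lower in mutant NPCs, and 39.05 would be expected by chance. limma-voom also called 0 (146 unadjusted), and DESeq2 called 93, of which 70 were higher and 23 lower. The groups did not overlap for 221 miRNAs, 28.3% of those tested, against 10% by chance for 3 libraries against 3. Counts were simulated once with the spread of these libraries, with 200 miRNAs changed and each row drawn independently. There the edgeR test recovered 4.48% of miRNAs changed 2-fold, 58.2% of those changed 4-fold and 92.4% of those changed 16-fold. It made 105 calls there and 0 in the real libraries, whose rows are not independent, so these percentages do not give its reach here.

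A few miRNAs took most of each library. miR-9-2-5p held 31.1% ± 1.24 of the counts in mutant and 23.8% ± 1.36 in wild-type libraries (SD, n = 3), and the 10 most abundant miRNAs held 74.6% ± 0.873 and 69.8% ± 4.66. In single libraries the share of miR-9-2-5p ran from 22.2% (95% exact binomial interval 22.225% to 22.25%) in wild-type library 1 to 32.4% (32.427% to 32.456%) in mutant library 1. The rows next in abundance were miR-21a-5p, let-7i-5p, miR-148a-3p and miR-99a-5p. They were at 70817, 72996, 50114 and 70592 CPM in mutant and at 76959, 71224, 74796 and 46148 CPM in wild-type NPCs, and none passed in edgeR or DESeq2.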

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

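The direction of miR-29b-1-3p held in every setting run, with a log2 fold change of 0.94 to 1.56, apart from the scale set by miR-29a-3p, where it was 0.13 (SE 0.39). It passed the threshold only in DESeq2 (1.32, adjusted p 0.012, against adjusted p values of 0.0912 to 0.763 elsewhere). The count of 0 changed miRNAs was also 0 with DESeq2 size factors, a minimum mean of 10 CPM, limma-voom and both doubted libraries left out. It was 8 with totals as the scale (7 higher, 1 lower), 30 with upper quartiles (27 and 3), 13 without a filter (11 and 2), 93 in DESeq2 (70 and 23), 1 with copies summed and 41 with the pluripotent list as covariate (18 and 23). The cause was not tested. With 1 library left out the count was 0 to 3 (1 without wild-type 2, 3 without wild-type 3). Scaling by totals moved the median log2 fold change of all miRNAs by -0.24. The miR-29b-3p to miR-29a-3p difference was -0.14 to 0.23 with 1 library left out.

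Replicate numbers showed no pairing of the libraries, as deviations of same-numbered libraries correlated at -0.382, -0.0815 and 0.0819. The highest value over all pairs of a wild-type and a mutant library was 0.372, between wild-type library 2 and mutant library 1. These values cannot exclude a shared batch, since the deviations were taken from means of only 3 libraries. With the replicate block 0 miRNAs passed (100 unadjusted), miR-29b-1-3p had 1.26 and 4 lists passed.

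4 lists passed camera with the preset correlation, 0 with an estimated correlation and 0 in fry. With the preset correlation 9 of 10 splits of the libraries, the real one among them, gave at least as many lists, and the highest other gave 9. The count of camera calls thus does not set the genotypes apart from other groupings. With 1 library left out, 4 to 6 passed (6 without wild-type 1, with the mesenchymal and sensory lists added, and 5 without wild-type 3, with miR-17 to 92 added). With both doubted libraries left out the neural list was lost (adjusted p 0.177) and the pluripotent list passed (3.75e-09).

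Some values that had not passed changed sign, and the cause was not tested. let-7i-5p was at -0.18 with totals and at -0.0045 with upper quartiles. In limma-voom miR-293-5p was at 1.53, miR-292-5p at 1.60 and miR-21a-5p at 0.0595, and with the block at 2.90, 2.52 and 0.0431. With both doubted libraries left out miR-293-5p was at 3.32, miR-292-5p at 3.27, miR-29b-2-5p at 0.0359, miR-210-3p at 0.0398 and miR-126-3p at 0.17. List signs changed for let-7 in fry (adjusted p 0.989), for the other degradation targets at 10 CPM (0.773), and for let-7 and miR-17 to 92 with both libraries left out (0.628 each). With 1 library left out the ranges were -0.12 to 0.25 for let-7i-5p, -0.38 to 0.10 for miR-126-3p, -0.47 to 0.38 for miR-21a-5p, -3.89 to 5.25 for miR-292-5p, -4.56 to 5.77 for miR-293-5p, -0.15 to 0.88 for miR-29a-5p, -0.21 to 0.0699 for miR-29b-2-5p and -0.62 to 0.36 for miR-29c-5p, and adjusted p values were 0.489 to 0.872 for let-7, 0.0393 to 0.906 for miR-17 to 92, 0.629 to 0.873 for the other degradation targets, 0.201 to 0.893 for the p53-linked and 1.17e-05 to 0.856 for the pluripotent list.

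Apart from leave-one-out fits, single miRNAs kept direction and side of the threshold in 430 values and passed in the same direction in 58. Shares of the most abundant miRNAs moved by less than their SD, which is no evidence of stability, as leaving out 1 of 3 libraries cannot move a mean further. Depth limits miR-29a-5p, with 8 to 40 counts per library, and miR-29b-1-5p, with 1 to 14.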

Other observations

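Several of the smallest p values lay outside the lists, in miRNAs picked after their values were seen. miR-708-5p had the smallest p of all miRNAs, at 23.8 ± 9.42 CPM in mutant and 1.41 ± 0.631 CPM in wild-type NPCs (SD, n = 3), 16.8-fold higher (edgeR adjusted p 0.0753, DESeq2 adjusted p 2.13e-11). Its other arm, miR-708-3p, was 7.70-fold higher. miR-135a-2-5p was 8.64-fold higher, at 102 ± 17.5 CPM against 11.9 ± 9.39 CPM. miR-204-5p went the other way, at 2.58 ± 1.04 CPM in mutant and 38.7 ± 31.7 CPM in wild-type NPCs, 14.9-fold lower. The groups did not overlap for any of these 4 miRNAs, and in edgeR the last 3 had an adjusted p of 0.0798.

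Neighbouring miRNA genes were grouped into 13 clusters of at least 5 tested rows. Both clusters of the Dlk1-Dio3 region had every row above 0, 40 of 40 from miR-379 to miR-376a and 14 of 14 from miR-127 to miR-665. In the Sfmbt2 cluster from miR-467a-9 to miR-466l, 38 of 39 rows were below 0 (camera adjusted p 5.48e-06). All 6 rows of the cluster of miR-27b, miR-23b and miR-3074-1 were below 0, with a median log2 fold change of -0.65, against -0.0993 for all tested miRNAs, and a camera adjusted p of 0.0145. These 4 clusters passed the set test, and 0 passed with an estimated correlation, where the miR-27b cluster had an adjusted p of 0.777. A further 5 clusters also had every row below 0, those starting with miR-881, let-7d, miR-292, miR-20a and miR-19b-2, and did not pass (camera adjusted p 0.0894 to 0.730). Among 211 hairpins with both arms measured, 1 changed its ratio of 3p to 5p arm past the adjusted threshold. This was miR-615, with a log2 difference of 4.56 (limma adjusted p 0.015), and 16 passed unadjusted. miR-29b was next by p, with 1.23 (SE 0.39, limma adjusted p 0.563).

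The tests below on miR-29, on the 2 lines, on the miR-290 cluster and on other splits at the adjusted threshold were chosen after the result was seen, as were the screens of clusters and of arm ratios.

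With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. At the adjusted threshold the real split and the highest other both gave 0, and a count of 0 cannot set the splits apart. At the unadjusted threshold the real split gave 164 miRNAs and the highest other 56, so 1 split, the real one, was as large. For lists in camera with the preset correlation the real split gave 4 and the highest other 9, with 9 of 10 splits as large. The count of lists called thus does not set the real split apart.

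miR-29a-3p and miR-29b-3p were both higher in mutant NPCs. For miR-29b, library scaling as the whole cause is argued against by the lowest log2 fold change of miR-29b-1-3p over 4 scalings, 1.08 ± 0.43 (SE, with totals as the scale). This test did not cover miR-29a-3p. Less decay of the guides would leave the passenger strands and more transcription would raise them too, and the guide to passenger difference was 0.65 ± 0.36 for miR-29a, within 2 SE of 0, and 1.23 ± 0.40 for miR-29b with its copies pooled, beyond 2 SE. The miR-29b ratio does not settle this. Both copies give the same guide sequence, so the row of a guide read does not show which copy it came from. The passenger counts come mainly from miR-29b-2-5p, and miR-29b-1-5p had 1 to 14 counts. A change of a single copy therefore cannot be followed. Slower decay of both guides and more transcription of the precursors both stay open, as these ratios do not tell them apart. miR-29c-3p (log2 fold change 0.45, SE 0.40) did not pass in either tool. Neither did miR-29b-2-3p (-0.67, SE 0.51), a scarce copy row of the same miR-29b-3p.

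The Dlk1-Dio3 miRNAs were 4.22-fold higher at the median in mutant NPCs. Counting noise of scarce miRNAs is argued against by the 18 rows with a mean of at least 10 CPM, all above 0 with a median of 2.03. The SE over these rows, 0.063, does not measure the spread between libraries, as rows of 1 region move together. Without wild-type library 2 and mutant library 1, 52 of 52 tested rows stayed above 0, with a median fitted log2 fold change of 2.39. The mean of the library medians then differed by 2.16 ± 0.87 on the log2 scale (SE, n = 2 in each group). This is less than 2 SE above the bound of 1, so other cells in these 2 libraries stay open as a part of the pattern. A difference between the 2 lines apart from the scrambled site, such as in the imprint of this region, may account for the pattern as well as the genotype. The lowest mutant library median lay 0.814 above the highest wild-type median on the log2 scale, and as the design text names 1 line for each genotype, with no word on the number of clones, the line and the site cannot be told apart.

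The miR-290 cluster was high in wild-type library 2 and mutant library 1. Reads carried over from wild-type library 2 are argued against as the whole source, because mutant library 1 held 22936 Sfmbt2 cluster counts. This was 10.8% (95% counting interval 10.68% to 10.96%) of the 211955 that carry-over in the proportion of the whole pluripotent cell list would bring. The Sfmbt2 cluster was high in wild-type library 2 alone. The sensory cluster was highest there too, at 13920 CPM of the library total, with 373.5 in wild-type library 3, 140.2 in mutant library 1 and 8.15 to 20.39 in the other 3 libraries. The source of the miR-290 counts stays open, and no biological explanation was tested.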
